A study of Homo sapiens with 12 samples.

How the data were processed

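ATAC-seq libraries of OSC19 cells were made from 150000 cells per replicate, per the labels' protocols, after 72 h in medium with 1% serum. There were 12 libraries in 4 groups of 3, namely vehicle, TCDD at 2 nM, Tryp, and Tryp with CH223191 at 1 µM. Groups and replicate numbers were taken from the sample titles. The library names number the vehicle libraries 1, 3 and 4 where the titles number them 1, 2 and 3, which is the numbering used. The treatment field of TrypCH 2 and TrypCH 3 gives another compound number than the titles and the protocol, and CH223191 is used here as these give it. Per the labels' protocols the cells were incubated with DNase before freezing. Tn5 tagmentation was done by a service company, with 10 PCR cycles and paired reads of 50 bp.

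The submitters' processing notes name the GRCh38 build and, among the tools, FastQC, Trim Galore, cutadapt, BWA, Bowtie2, SAMtools, bedtools, deepTools, MACS2 and HOMER. Their roles, order, versions and settings, duplicate removal and any shift of the read ends for the Tn5 insertion are not given in the sources used here. The authors called peaks per library and deposited 1 list for each, so a library is a replicate and no list pools samples. The deposited fold enrichment of a peak is a ratio at its summit over the local background of its own library. It is the authors' own value and was used to solve the background density of a list. At some regions it is also set side by side between libraries, without a test. The deposited −log10 p and −log10 q are those of the peak within its library, and the smallest −log10 q was 1.00. The deposited score is 10 times the −log10 q, rounded down. Per the file headers, HOMER annotated each library's own peaks against the nearest transcription start, in bp. The authors' motif tables give, per the file headers, the count of 1000 target sequences with each known motif and an estimated count of background sequences, which is weighted and need not be whole. They also give both as percent, with a p-value, its natural log as a score, and a Benjamini q-value. How the 1000 sequences were chosen is not given in the sources used here. The deposited p-values, scores and q-values of motifs were not compared between libraries.

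Whether a region was called depends on depth, on fragment length and on the caller's threshold, and the lists hold no read totals. The background fragment density of each library was therefore solved from the fold and p of 4000 peaks under the Poisson model of the peak caller, within 0.001 of the −log10 p. No count of fragments per region was available, so no count model was used and no interval for counting error is given. Calls were analysed as present or absent.

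Peaks on chromosomes 1 to 22, X and Y were merged into union regions where they overlapped by at least 1 bp, and a region was called in a library with any overlapping peak. Between 0.294% and 0.350% of each list lay on other contigs and was left out. Libraries were compared by the Jaccard index of called base pairs, with a permutation test of 100000 random assignments. A conditional Rasch model, in which each library has its own calling rate, gave the number of regions expected to be called in all 3 libraries of a group and no library of another. The same model over 12 libraries gave the probability of each call in regions called in 1 to 11 libraries. For each gene the calls minus these probabilities were summed over the regions annotated to it as the nearest gene, within 100 kb of its transcription start. A region thus counted for 1 gene only. The 13628 genes with at least 3 such regions were tested in limma with trend, with 4 groups in a fit of all 12 libraries, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Motifs with a mean target percent of at least 1 (847 of 1004 with a unique name) were tested in the same way on the log2 ratio of target to background percent, after adding 0.01 to each.

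The comparisons were Tryp with vehicle, TrypCH with Tryp, TCDD with vehicle and TrypCH with vehicle. The agonist contrast set the 6 TCDD and Tryp libraries against the 6 vehicle and TrypCH libraries, where regions called in at least 5 of 6 and at most 1 of 6 were counted. Single values were compared by two-sided exact permutation tests. Overlaps of region sets were tested by Fisher's exact test, two-sided, over regions called in 1 to 11 libraries. Overlaps that share the vehicle libraries were set beside 100 simulations of unchanged groups.

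The 22 gene lists were fixed before the data were examined, as were the tests, the naming rule and all alternatives except those said to be added. They were the AHR target battery, AHR pathway components, tryptophan metabolism and transport, NRF2 antioxidant, basal squamous identity, keratinocyte differentiation, mesenchymal transition, epithelial junction and simple keratins, matrix proteases, inflammatory cytokines, interferon and antigen presentation, immune checkpoints, AP-1 and MAF factors, YAP-TEAD and TGF-beta, cell cycle, stemness, chromatin regulators and housekeeping. Markers of fibroblasts, immune cells, endothelium and neurons stood for cell types not meant to be present. Of 329 list entries 324 were found in the annotation, 7 of them by an older symbol. A list's value was the mean, in percentage points, of calls minus probabilities over its regions.

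Named genes were chosen by rule. In each comparison these were the AHR battery genes with a region within 100 kb, and the 8 genes with the most positive and the 8 with the most negative limma statistic past the threshold. Where fewer than 5 passed in a direction, the 5 largest were taken and said not to have passed. The rule also took the 8 gained and 8 lost regions whose lowest percentile of −log10 q over the calling libraries was highest, and 12 in each direction for the agonist contrast. Of the motifs, it took those of AHR, ARNT, HIF, NPAS, NRF2, AP-1, p63, TEAD and CTCF and the 5 largest past the threshold. The text gives a part of the regions and motifs that the rule took, and other names are said to be chosen after their values were seen.

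Alternatives were peaks with a −log10 q of at least 5 (stricter peaks), the 97771 strongest peaks of each library (lists of equal number), at least 50% of a region covered, merged windows of 500 bp around summits, other criteria for gains and losses, 50 kb in place of 100 kb, at least 1 or 5 regions per gene, raw numbers of regions, promoters only (within 1 kb), other motif scales and filters, a pseudocount of 0.1, peak number as a covariate, only the groups compared, all contigs, a replicate block, and each library left out. Peaks of at least 211 bp (wide peaks), the widest of the smallest widths, TCDD by its first library alone, a limma fit over the lists and Fisher's exact test of list regions among gained and lost regions, which was not used as a result, were added after the data were seen.

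The steps were tested on simulated data. With no difference between groups, observed over expected counts of gained and lost regions averaged 0.993 for Tryp against vehicle, 1.01 for TrypCH against Tryp, 1.01 for TCDD against vehicle and 1.01 for TrypCH against vehicle, in 20 simulations each over 211696 regions. These calls were drawn from the Rasch model itself. Values near 1 therefore check the computation and not whether the model describes the real lists. In a simulation of TCDD against vehicle over 13628 genes with 200 changed, 1 of 100 genes at odds multiplied by 4 and 16 of 100 at odds multiplied by 20 passed, and 0 of the 13428 others. The changed genes were drawn from those with at least 5 regions. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. A search for sequence motifs in gained regions, planned before the data were examined, was left out because it needs a genome, which was not used here.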

Results

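Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in OSC19 cells, an established human line from a squamous cell carcinoma of the tongue. Cells were kept for 72 h in medium with 1% serum under 4 conditions, each with 3 libraries. The conditions were the DMSO vehicle, TCDD at 2 nM, a pool of tryptophan metabolites (Tryp), and that pool with CH223191 at 1 µM (TrypCH). TCDD (dioxin) is a potent and persistent agonist of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. CH223191 is an antagonist of AHR. Several metabolites of tryptophan are AHR ligands, and the labels set out to find how sustained exposure to such metabolites alters chromatin in head and neck cancer cells. The metabolites in the pool and their doses are not given in the sources used here. Nothing states that the libraries of a group came from separate cultures. The p-values of tests across libraries therefore measure only the spread between these libraries, which may be technical. Fisher's exact tests of overlaps treat regions as independent and hold no spread between libraries.

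Each library had its own list of called peaks, between 97771 in Tryp 2 and 164955 in TCDD 2 on the autosomes, X and Y. Read totals are not in the lists, so a fragment total was not known for any library. The mean number of peaks was 124935 ± 6855 (SD, n = 3) for vehicle, 147596 ± 26362 for TCDD, 124349 ± 23867 for Tryp and 147590 ± 7351 for TrypCH. Two-sided exact permutation tests gave p = 0.9 for Tryp against vehicle, 0.2 for TrypCH against Tryp, 0.4 for TCDD against vehicle and 0.1 for TrypCH against vehicle, with 0.1 the smallest p that 3 against 3 libraries allow. Adjusted p-values over these and the contrast of all 6 agonist libraries were 0.983, 0.5, 0.667 and 0.5. The difference of Tryp from vehicle, -586 peaks, was 2971 without vehicle 2 and 12703 without Tryp 2. The smallest peak width was 114 bp in TCDD 2 and 111 bp in TCDD 3, against 142 bp in TCDD 1 and 211 bp in Tryp 2. In MACS2, by default, this width is the fragment length that the caller estimates, and the submitters' settings are not given in the sources used here. The background fragment density solved from each list lay between 1.26 fragments per base in Tryp 2 and 2.35 in TrypCH 3. Divided by the smallest width and set relative to the vehicle mean, it was 0.470 in Tryp 2 and 1.46 in TrypCH 3, which stands for fragment numbers only if that width is the fragment length.

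**Figure D1:**
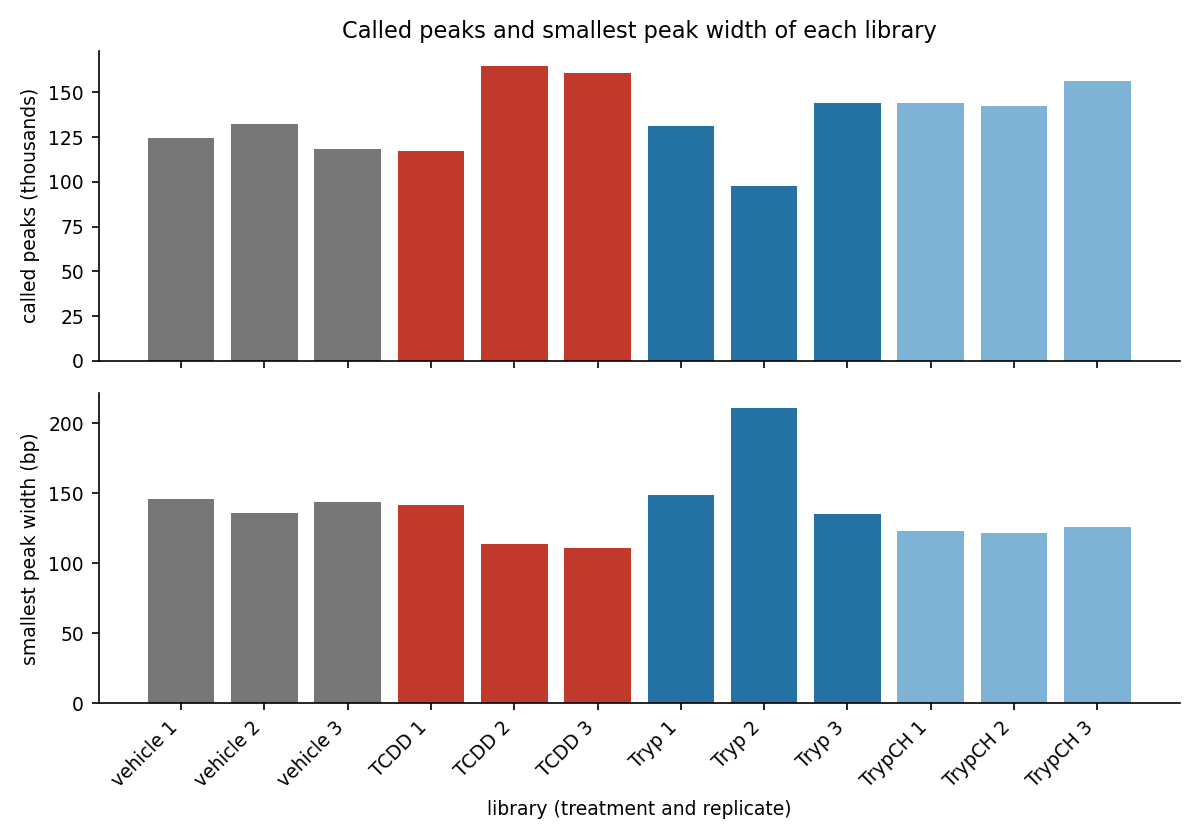
Called peaks (top, axis in units of 1000) and smallest peak width in bp (bottom) for each of the 12 libraries, in bars coloured by treatment. Tryp 2 has the fewest peaks (97771) and the widest minimum (211 bp), and TCDD 2 and TCDD 3 have the narrowest minimum (114 and 111 bp).

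Peaks of the 12 libraries merged into 211696 union regions, of which 78619 (37.1%) were called in all 12. Averaged over pairs, libraries of the same treatment shared more called sequence than libraries of different treatments. The Jaccard index of called base pairs was 0.703 ± 0.0462 (SD over 12 pairs of libraries) within treatments and 0.670 ± 0.0407 (54 pairs) between them, and a permutation test of the difference of 0.0331 gave p = 0.00207. This did not hold for each treatment. The index was 0.750 within TrypCH and 0.718 within vehicle, but 0.674 within TCDD and 0.669 within Tryp. Those of vehicle with TrypCH (0.703), vehicle with Tryp (0.694) and Tryp with TrypCH (0.679) lay above the last pair of values, and that of TCDD with Tryp (0.627) was the lowest. TCDD 2 and TCDD 3 had 0.747 with each other, but TCDD 1 had 0.639 and 0.635 with them. With vehicle 1, 2 and 3, TCDD 1 had higher values, 0.694, 0.660 and 0.672. The index was not adjusted for list length or peak width.

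The comparison of Tryp with vehicle asks which regions respond to the metabolites. A region upstream of CEACAM6, a cell adhesion molecule of epithelial cells, was called in 3 of 3 Tryp and 0 of 3 vehicle libraries (chromosome 19, 41753791 to 41754340, GRCh38, intergenic, -1447 bp from the transcription start). It was called in 0 of 3 TrypCH and 1 of 3 TCDD libraries. A region in intron 3 of EXT2, a heparan sulfate polymerase (chromosome 11, 44110171 to 44110492), was also called in 3 Tryp and 0 vehicle libraries, as were intergenic regions nearest to MEF2C and FSTL5. These last 3 regions were called in 3 of 3 TrypCH libraries too, as were 6 of the 8 gained regions ranked highest, and CEACAM6 was the only one of the 8 called in no TrypCH library. In the other direction, regions near CRELD2 (chromosome 22, 49929630 to 49929896) and in intron 1 of ABL2 (chromosome 1, 179141897 to 179142181) were called in all 3 vehicle libraries and no Tryp library. None of the genes of the AHR target battery, the list of known AHR targets, had a region of either kind. Of all 211696 union regions 717 were of either kind, and the battery had 135 regions, so this 0 says little.

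In total 399 regions were called in all 3 Tryp and no vehicle library, and 318 the other way, where a model of the libraries' overall calling rates expected 237 and 370. The observed total was 1.18 times the expected total. These counts rise when a library is left out, since fewer calls then define them. Gains were 969, 965 and 695 without vehicle 1, 2 and 3, 885 without Tryp 1, 3378 without Tryp 2 and 736 without Tryp 3. Tryp 2 had the lowest calling odds of all libraries in the model (0.117). A region that it missed could not count as a gain, so this library limits the number of gains. Losses were 909, 771 and 1365 without vehicle 1, 2 and 3, 1042 without Tryp 1 and 1480 without Tryp 3.

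At the level of genes, each region counted only for the gene with the nearest transcription start, within 100 kb. The number of called regions was compared after adjustment for each library's calling rate, and the values below are in regions per gene. No gene of 13628 passed an adjusted p of 0.05 in limma, and 829 had an unadjusted p under 0.05. Ranked by the limma statistic, the first genes with positive values, which did not pass, were ADAM28 (4.30 ± 0.722 SE, adjusted p = 0.223), LOC100129316 (3.08), CHL1-AS1 (3.29), GNAQ (3.94) and MIR4472-2 (3.36). The first with negative values were LINC01018 (-3.88), TIPARP-AS1 (-4.45), CRYBB3 (-3.02), LINC00674 (-2.54) and TTC34 (-4.69). TIPARP-AS1 lies beside TIPARP, which encodes a repressor of AHR. Of the 10 battery genes tested, 0 passed over all genes and 0 adjusted over the list alone. Their values ran from -1.79 for the amino acid transporter gene SLC7A5 and -1.59 for AHRR, the AHR repressor, to 0.338 for CYP2S1. In other lists 4 genes passed when adjusted over the list alone, and they were chosen after their values were seen: KRT8 (-1.99), BATF3 (1.92), ACTB (-2.55) and THY1 (-1.92). With lists of equal number KRT8 was 0.00457, and with wide peaks 0.108. Without vehicle 1, vehicle 3 or Tryp 2 the number of genes past the threshold was 1, 2 and 1.

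No known motif of 847 tested passed in the authors' motif tables for Tryp against vehicle, where limma gave 74 at an unadjusted p under 0.05. The Arnt:Ahr motif, the sequence bound by AHR with its partner ARNT, had a log2 ratio difference of -0.016 (adjusted p = 1.00). The Nrf2 motif had 0.20 and NFE2L2, a motif of the same factor, -0.091, and TEAD, p63 and AP-1 motifs lay between -0.10 and 0.032. Without TCDD 1 or Tryp 1 the number of motifs past the threshold was 1 and 2.

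The comparison of TrypCH with Tryp asks what the AHR antagonist changes in the presence of the metabolites. The CEACAM6 region led the regions called in all 3 Tryp and no TrypCH library, followed by a region in intron 1 of LIFR (chromosome 5, 38551225 to 38551737), the receptor of leukaemia inhibitory factor. Regions in intron 1 of MACF1 and intron 8 of IL31RA were likewise called in 3 Tryp and 0 TrypCH libraries, and both were called in all 3 TCDD libraries. They were also called with vehicle, MACF1 in 3 of 3 and IL31RA in 2 of 3 libraries. Regions called in all 3 TrypCH and no Tryp library included intron 13 of HECTD4 (chromosome 12, 112267166 to 112267305), intron 12 of FERMT2 (chromosome 14, 52863090 to 52863238) and the CRELD2 region.

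There were 2805 regions called in all TrypCH and no Tryp library (1642 expected) and 218 called the other way (42.5 expected), a total of 1.79 times the expected one. In lists trimmed to the same number of strongest peaks per library, the counts were 723 and 866. Gains were 4923 without Tryp 1, 7903 without Tryp 3, 4980 without TrypCH 1 and 5202 without TrypCH 2. Losses were 469, 1325 and 520 without Tryp 1, 2 and 3, 372 without TrypCH 1 and 663 without TrypCH 3.

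EPAS1, which encodes the hypoxia factor HIF-2α, ranked first by the limma statistic in this comparison, with 5.82 ± 0.872 (SE) more called regions with the antagonist. It did not pass (limma, adjusted p = 0.0563). COL13A1 (3.87), LOC101929680 (2.86), CALM2 (2.64) and THY1 (2.80) followed in that ranking, and CLLU1OS (-3.66), TFEC (-3.41), IRAK2 (-2.65), LOC285692 (-5.50) and PKI55 (-2.78) led in the negative direction. No gene passed over all genes and 1006 had an unadjusted p under 0.05. Without vehicle 1, 2 or 3 the count was 3, 2 and 1, and without Tryp 2 or TrypCH 2 it was 1. In the battery AHRR had 2.02 ± 0.687 (unadjusted p = 0.00938, adjusted p = 0.531), CYP1B1 -0.781 and CYP1A1 -0.406, and 0 genes passed adjusted over the list alone. Genes chosen after their values were seen, which passed adjusted over the list alone, were OSGIN1 (2.11), CCND1, the cyclin D1 gene (3.51), THY1, SMAD7 (-2.05) and HPRT1 (-1.88). With lists of equal number CCND1 was -0.245, THY1 -0.543 and LOC285692 0.198, and with wide peaks COL13A1 was -0.300. Among motifs only MYB57, a plant factor's motif, passed (log2 ratio -0.34, limma adjusted p = 0.0247), and 8 libraries (TCDD 1, TCDD 3 and those of Tryp and TrypCH) each left 0 motifs when removed. The count of 1 was also 0 with only the libraries compared and with peak number as a covariate, and 2 without the filter. TEAD1 (0.22) had the highest value of the motifs fixed in advance, followed by NFE2L2 (0.21) and TEAD3 (0.20), and 0 of these 18 passed adjusted over the list alone.

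The comparison of TCDD with vehicle asks which regions differ after a strong agonist. CYP1A1, a xenobiotic-metabolising enzyme and the best known AHR target, had a called region in exon 7 (chromosome 15, 74719785 to 74720324) in 3 of 3 TCDD, 1 of 3 vehicle and none of the 6 Tryp and TrypCH libraries. These were weak peaks, with authors' folds of 1.88, 1.99 and 1.70 in the TCDD libraries and 2.78 in the vehicle library that called it. A region in intron 1 of CYP1A1 (74724045 to 74724365) was called in 3 TrypCH, 1 Tryp and no TCDD or vehicle library. The promoter of SERPINB2, which encodes a plasminogen activator inhibitor (chromosome 18, 63887483 to 63887791), was called in all 3 TCDD libraries and none of the other 9. Intron 1 of EREG, the gene of the growth factor epiregulin (chromosome 4, 74377614 to 74378079), behaved likewise, and intron 2 of SERPINB2 (63893858 to 63894752) was called in 3 TCDD, 1 Tryp and no other library. At the intergenic region -6552 bp from the CYP1A1 start (chromosome 15, 74731733 to 74732454), called in all 12 libraries, the authors' fold over each library's own background was 23.9, 31.3 and 30.3 with TCDD. It was 9.95 to 12.5 with vehicle, 10.6 to 17.8 with Tryp and 11.3 to 13.9 with TrypCH. The fold at the CYP1B1 promoter was 15.4 to 17.2 with TCDD against 10.9 to 11.7 with vehicle, and at the CYP2S1 promoter 6.10 to 6.72 against 10.1 to 11.9. These folds describe each library and were not tested, and no rule set in advance chose these regions.

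**Figure D2:**
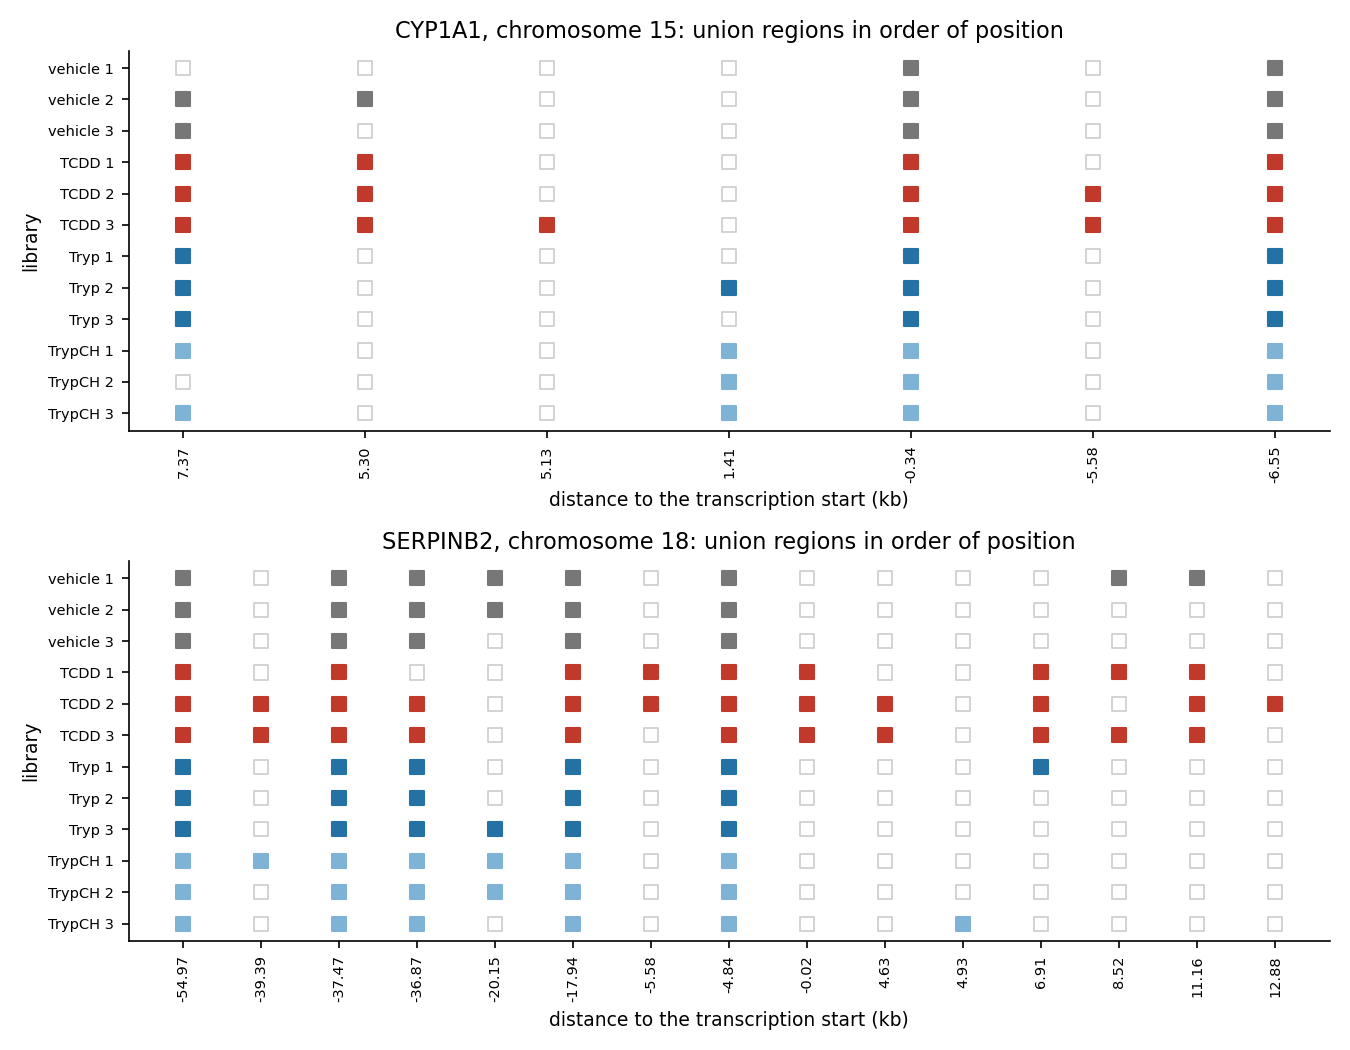
Union regions near CYP1A1 (top) and SERPINB2 (bottom) in order of position along the horizontal axis, labelled with the distance to the transcription start in kb, against the 12 libraries; a filled square marks a called region and an open square a region not called. The SERPINB2 promoter region is filled in all 3 TCDD libraries and in none of the other 9.

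Outside the battery, the highest ranked gain was in intron 3 of STK35, a kinase gene (chromosome 20, 2131345 to 2131645), called in 3 TCDD and none of the other 9 libraries. Other high ranks included regions nearest to LEFTY2, TSPAN8 and FHAD1. Regions lost with TCDD and called in all 9 other libraries lay in intron 3 of EGFEM1P (chromosome 3, 168341145 to 168341757), in exon 19 of PTPN14 (chromosome 1, 214349839 to 214350252), in intron 1 of ABCA8 and in intron 11 of SLC28A1. In total 4900 regions were called in all TCDD and no vehicle library (1680 expected), and 1152 the other way (137 expected), 3.33 times the expected total. Gains were 1.39% promoters and losses 1.56%, against 2.10% of the regions called in 3 of these 6 libraries in other patterns and 5.85% of all union regions, and these shares were not tested. In lists of equal number the counts were 2734 and 2853, 5.75 times the expected total. Gains were 15556 without TCDD 1. Losses were 2126 without vehicle 1, 2039 without vehicle 3, 1941 without TCDD 2 and 1813 without TCDD 3.

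**Figure D3:**
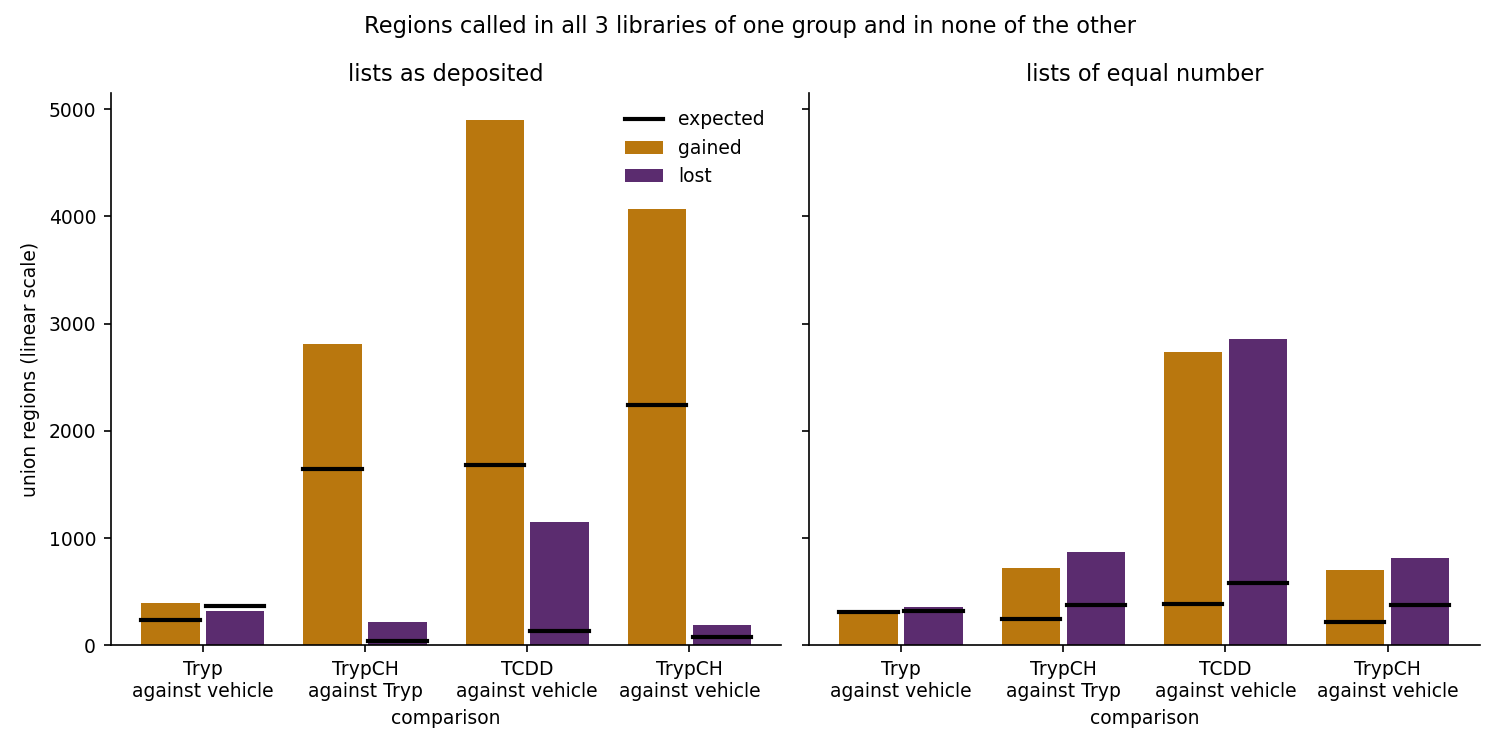
Number of union regions called in all 3 libraries of one treatment and none of the other (gained and lost, bars) in 4 comparisons, for the lists as deposited (left) and trimmed to equal number (right); black lines give the number expected from the libraries' calling rates. For TCDD against vehicle the bars reach 4900 and 1152 on the left and 2734 and 2853 on the right.

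In the gene-level test 30 genes passed in TCDD against vehicle, 15 with more called regions and 15 with fewer, and 1952 had an unadjusted p under 0.05. Genes with more were LOC100129316 (4.81 ± 0.566 SE, limma adjusted p = 0.00236), SCGB1C2 (4.13), LINC00557 (3.34), OR4F21 (4.40), the haematopoietic transcription factor gene GFI1 (4.50), LOC101927637 (3.04), BTBD11 (4.15) and LINC01252 (3.12). Genes with fewer were GPC4, a cell surface heparan sulfate proteoglycan (-3.82 ± 0.578, adjusted p = 0.0225), MIR4279 (-4.74), MIR663A (-4.83), CRYBB3 (-3.63), NRK (-3.64), PSD2 (-3.44), RNU6ATAC (-4.41) and LOC101927460 (-3.82). SMARCA4, the ATPase of the SWI/SNF chromatin remodelling complex, also passed (-2.99, adjusted p = 0.0442), and was chosen after its value was seen. With stricter peaks PSD2 was 0.287, and with lists of equal number RNU6ATAC was 0.411. The count of 30 was 13, 4 and 1 without vehicle 1, 2 and 3, 1 and 0 without TCDD 2 and 3, 11 without Tryp 2, and 2 and 9 without TrypCH 1 and 2. It was 0 within 50 kb, 1 with only the 6 libraries compared, 2 with raw numbers of regions, 18 with at least 1 region per gene, 2 with TCDD by its first library alone, 63 with wide peaks, 131 with stricter peaks and 245 with lists of equal number.

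Battery genes split evenly, 5 above and 5 below 0 of the 10 tested. SERPINB2 had 2.54 ± 0.788 (adjusted p = 0.148), EREG 2.28, CYP1A1 1.23, CYP1B1 0.959, ALDH3A1 -0.872 and SLC7A5 -1.02. None passed over all genes, and 0 passed adjusted over the list alone, where SERPINB2 stood at 0.050, just above the threshold. With wide peaks AHRR was 0.786, ALDH3A1 0.0833, CYP2S1 0.0881 and NQO1 -0.264, each of the other sign. Genes of other lists that passed adjusted over the list alone are named here after their values were seen. Keratin 8, KRT8, of simple epithelia had -3.08 (adjusted over the list alone, 0.000509), and the mesenchymal transition factor gene TWIST1 2.53. Among 11 cytokine genes tested, CXCL8 (2.28), IL1A (1.78) and IL33 (3.02) passed, and among 10 cell cycle genes CCNE1 (3.30) and CDK1 (-4.03). Of 16 chromatin regulators SMARCA4 and EED (-2.15), a Polycomb subunit, passed. Markers of cell types not meant to be in the culture passed too, with LUM (-2.20), CD2 (2.77), CDH5 (-2.73), CLDN5 (-2.34), EMCN (1.71) and MAP2 (-2.41). With lists of equal number KRT8 was 0.0543 and CLDN5 0.409, and with wide peaks CXCL8 was -0.915.

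Of 847 motifs, Zic2 passed in TCDD against vehicle (log2 ratio 0.34, limma adjusted p = 0.00193). The Nrf2 motif of the antioxidant response had 0.49 ± 0.111 (adjusted p = 0.0780), the NFE2L2 motif of the same factor 0.24 (0.507), AP-1 0.36 (0.0873) and Arnt:Ahr 0.26 (0.116). These did not pass over all motifs, and of the 18 motifs of families fixed in advance Nrf2, AP-1 and Arnt:Ahr were the 3 that passed adjusted over the list alone. The count of 1 was 52 without TCDD 1 and 6 without Tryp 2, 17 on the logit scale, 4 without the filter, and 0 with only the libraries compared or with TCDD by its first library alone.

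TrypCH was also compared with vehicle. A region at the promoter of WDR59 (chromosome 16, 74985851 to 74986138) was called in 3 vehicle and 0 TrypCH libraries, as was one upstream of FSCN1, the gene of the actin bundling protein fascin (chromosome 7, 5571600 to 5572121). Regions upstream of TGM3, an epidermal transglutaminase (chromosome 20, 2284122 to 2284266), and of FGF19 (chromosome 11, 69713364 to 69713600) were called in 3 TrypCH and 0 vehicle libraries. There were 4066 such gains (2244 expected) and 185 losses (78.6 expected), and 702 and 812 in lists of equal number. Gains were 7434 without vehicle 2, 6717 without TrypCH 1 and 7125 without TrypCH 2. Losses were 469, 533 and 866 without vehicle 1, 2 and 3 and 337, 288 and 564 without TrypCH 1, 2 and 3.

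No gene passed in TrypCH against vehicle (limma), and 1129 had an unadjusted p under 0.05. PLCG2, a phospholipase of immune receptor signalling (-4.23, adjusted p = 0.0712), LINC01214 (3.85), CDC42BPA (3.10) and ATXN1 (3.55) came closest, followed by MROH5 (-5.11), SAMD4A (-3.36), TIPARP-AS1 (-4.53), BANF2 (-4.04), PDLIM2 (2.67) and CHL1-AS1 (3.13). With lists of equal number ATXN1 was -0.0833 and BANF2 0.481. The count was 1 without vehicle 2 and 8 without vehicle 3. Battery genes ran from -1.68 for SERPINB2 and -1.15 for SLC7A5 to 1.18 for CYP2S1, and 0 of 10 passed adjusted over the list alone. SERPINB2 was 0.0560 and SLC7A5 0.0888 with lists of equal number. COL1A2 (3.92, -1.18 with wide peaks) and RBFOX3 (-3.58), named after their values were seen, passed adjusted over the list alone. The composite bZIP:IRF motif passed (log2 ratio 0.55, limma adjusted p = 0.00651). The count of 1 was 3 without Tryp 1, 2 without Tryp 2 and 0 without TrypCH 2. It was 0 on the logit scale, 6 without the filter, and 2 with a pseudocount of 0.1, with peak number as a covariate or with the replicate block. The Nrf2 motif had 0.40 ± 0.111 (limma adjusted p = 0.268), near its 0.49 in TCDD against vehicle, and NFE2L2 had 0.11. Of the 18 motifs of families fixed in advance, 0 passed adjusted over the list alone.

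The agonist contrast assumes that the pool activates AHR and that CH223191 blocks this, which was not tested. A change that depends on AHR would then be present with TCDD and Tryp and absent with vehicle and TrypCH. The 6 libraries with an agonist and no antagonist were therefore set against the other 6. Regions higher with agonist were led by intron 12 of TASP1 (chromosome 20, 13422724 to 13422954), and included intron 2 of GNAQ, a G protein subunit gene (chromosome 9, 77907704 to 77907877). Regions lower with agonist included one at the end of SBF1 (chromosome 22, 50444670 to 50444928) and one in intron 1 of LIMS1 (chromosome 2, 108616820 to 108617163). No region near a battery gene met the criterion of at least 5 of 6 against at most 1 of 6 libraries. That criterion was met by 538 regions (196 expected) in the agonist direction and 652 (251 expected) in the other, 2.66 times the expected total. These 1190 are few of the 133077 regions called in 1 to 11 libraries. The battery had 81 such regions, so 0 near its genes says little. The regions higher with agonist numbered 869 without vehicle 1, 946 without TCDD 1, 1549, 2124 and 970 without Tryp 1, 2 and 3, and 1075 without TrypCH 3. Those lower numbered 1493, 1147 and 1447 without vehicle 1, 2 and 3, 1133 and 1103 without TCDD 2 and 3, and 1545 and 1696 without Tryp 1 and 3. Fisher's exact test region by region gave 0 of 133077 past the adjusted threshold and 425 at an unadjusted p under 0.05. The smallest p that 6 against 6 libraries allow there is 0.00216, which 9 regions higher and 11 lower with agonist reached with an adjusted p of 1, so this 0 says nothing about the regions.

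At the gene level 19 genes passed in this contrast, 14 with more called regions under agonist and 5 with fewer, and 1614 had an unadjusted p under 0.05. Genes with more were LOC100129316 (3.59 ± 0.400 SE, limma adjusted p = 0.00109), LINC00557 (2.52), the metalloprotease gene ADAM28 (3.29), MIR583 (2.80), RRN3P2 (2.82), PKI55 (2.47), LOC100289673 (2.46) and APCDD1L-AS1 (2.06). Genes with fewer were RBMS3-AS3 (-1.92), CRYBB3 (-2.34), MIR663A (-3.07), EPAS1 (-3.32, adjusted p = 0.0472) and MIR4279 (-2.69). With wide peaks MIR4279 was 0.305 and RBMS3-AS3 0.153, and within 50 kb EPAS1 was 0.0696. The count of 19 was 5, 7 and 0 without vehicle 1, 2 and 3, 2 without TCDD 2, 8, 7 and 7 without Tryp 1, 2 and 3, and 2, 3 and 11 without TrypCH 1, 2 and 3. It was 0 with raw numbers of regions, 1 within 50 kb, 4 with at least 1 region, 31 with at least 5, 3 with TCDD by its first library alone, 6 with wide peaks, 57 with lists of equal number and 70 with stricter peaks. Battery genes ran from -1.14 for AHRR to 1.69 for SERPINB2, and 0 of 10 passed adjusted over the list alone. Named after their values were seen, genes of other lists that passed adjusted over the list alone were TWIST1 (2.02), MMP2 (1.20), SNAI1 (-1.09), ZEB1 (-1.23), KRT8 (-1.98), CXCL8 (2.02), IL33 (2.31), CCND1 (-2.95), ALDH1A3 (2.97), EED (-1.81), ACTB (-1.28), HPRT1 (1.20), THY1 (-1.30) and CD2 (2.28). With lists of equal number CCND1 was 0.00376, ALDH1A3 -0.323 and THY1 0.506, and with wide peaks CXCL8 was -0.175. No motif passed (limma), and 96 had an unadjusted p under 0.05, with AP-1 at 0.16 and TEAD1 at -0.14. Without vehicle 1 the count was 1.

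Regions gained with TCDD over vehicle and regions higher in Tryp than in TrypCH, comparisons with no library in common, shared 9 regions where independent lists give 8.03 (Fisher's exact test, two-sided, p = 0.717). The exact 95% Poisson interval of that overlap was 4.12 to 17.1. Regions lost with TCDD and lower in Tryp than in TrypCH shared 11, fewer than the 24.3 of independent lists (Fisher's exact test, p = 0.00372). The calling rates of the 12 libraries give 3.12 such regions, and with lists of equal number the overlap was 24 against 31.2 of independent lists (Fisher's exact test, p = 0.230). It stayed lower at 50% cover, with 18 against 51.1, and with stricter peaks, with 11 against 32.6. With at least 2 of 3 libraries it lay close to the number of independent lists, as given below. For the first overlap the calling rates give 1.56. It was 281 against 244 with at least 2 of 3 libraries (Fisher's exact test, p = 0.0116) and 25 against 44.7 at 50% cover (Fisher's exact test, p = 0.00168). Without vehicle 1 or 2, Tryp 1, 2 or 3, or TrypCH 2 or 3, the first overlap was 25, 16, 35, 97, 17, 15 and 36. Without vehicle 1, 2 or 3, TCDD 2 or 3, Tryp 1 or 3, or TrypCH 1 or 2, the second was 41, 25, 38, 18, 18, 58, 72, 19 and 19. Measured each against the same vehicle libraries, TCDD and Tryp shared 113 gained and 45 lost regions. Unchanged groups simulated against those vehicle libraries shared 80.9 and 33.4 on average and at most 105 and 46, and independent lists give 14.7 and 2.75. Unchanged groups with these shared controls thus gave most of the excess over independent lists. The 45 shared losses lay below the simulated maximum and the 113 shared gains above it. With 3 vehicle libraries no split leaves 2 in each part, so the controls could not be separated. Without vehicle 1, 2 or 3, TCDD 1, Tryp 1 or Tryp 2 the shared gains were 409, 318, 205, 202, 204 and 753. Without vehicle 1, 2 or 3, TCDD 2, Tryp 1 or Tryp 3 the shared losses were 252, 184, 349, 72, 142 and 138.

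The gene lists fixed in advance were compared by the share of their regions called above expectation, in percentage points, for the 6 agonist libraries minus the other 6. Chromatin regulators had the most negative value, -9.42 points (exact permutation p = 0.00649, adjusted p = 0.143), and epithelial junctions and simple keratins followed at -7.09. Inflammatory cytokines had the highest value, 10.7 points. No list of 22 passed the adjusted threshold, and 5 had an unadjusted p under 0.05, the others being cell cycle genes at -5.73 and immune cell markers at 6.45. With lists of equal number these last values were 4.85 and -2.96, and fibroblast markers turned to 1.37. The AHR target battery stood at 0.598 (exact permutation p = 0.903), with 7.44 ± 4.87 points (SD, n = 3) in TCDD, 2.01 ± 6.03 in vehicle, -6.84 ± 7.56 in Tryp and -2.61 ± 2.91 in TrypCH. Of the battery's 135 regions, the 81 called in 1 to 11 libraries entered these values. The remaining lists, none past the threshold, were fibroblast markers at -7.04, housekeeping genes at -4.55, AP-1 and MAF factors at -4.16, AHR pathway components at -3.05, keratinocyte differentiation at -2.60, interferon and antigen presentation at -2.60, immune checkpoints at -2.13, matrix proteases at -0.806 and the YAP-TEAD and TGF-beta list at -0.201. Above 0 lay mesenchymal transition at 3.15, tryptophan metabolism and transport at 2.79, basal squamous identity at 1.29, stemness at 1.14, neuronal markers at 1.11, NRF2 antioxidant genes at 1.08 and endothelial markers at 0.282. With stricter peaks 3 lists passed. A limma fit over the lists, chosen after seeing the data, called chromatin regulators alone (adjusted p = 0.0135).

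**Figure D4:**
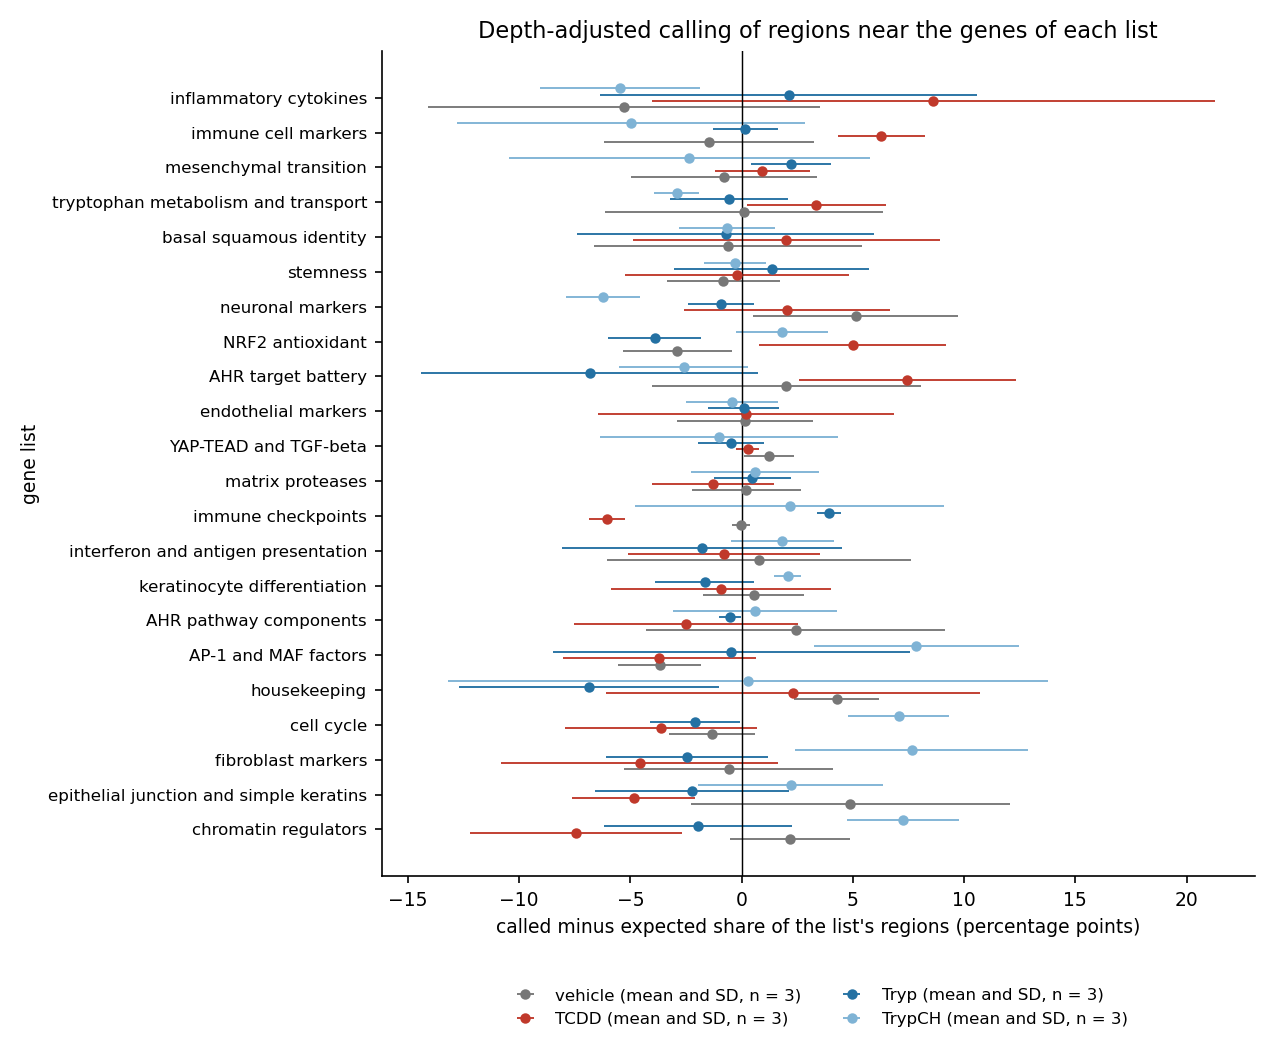
Called minus expected share of each list's regions in percentage points (horizontal axis) for the 22 gene lists, with points at the mean and bars at the SD of the 3 libraries of each treatment. Chromatin regulators stand lowest in TCDD (-7.44 points) and high in TrypCH (7.26 points), and no list passed the adjusted threshold.

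Shares of peaks in annotation classes were close between treatments. Promoters made up 8.71% ± 0.420 (SD, n = 3) of peaks in vehicle, 8.31% ± 0.555 in TCDD, 8.85% ± 1.20 in Tryp and 8.22% ± 0.443 in TrypCH. For the 6 agonist libraries against the others, the exact permutation test passed for 0 of 5 classes and gave 0 at an unadjusted p under 0.05, the smallest p being 0.128 for exons. Exons made up 4.70% ± 0.0181 of peaks in vehicle, 4.52% ± 0.142 in TCDD, 4.43% ± 0.124 in Tryp and 4.49% ± 0.0685 in TrypCH. Each of the 3 against vehicle gave an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow, and no other class reached it in these comparisons.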

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

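The wide peaks, the fit of TCDD by its first library alone, the limma fit over lists and Fisher's test of list regions were chosen after seeing the data, and the other alternatives before the data were examined. Of the results that answer a comparison, 111 values under an alternative other than leaving out a library were alike, 81 moved and 5 turned. A test was alike if it kept its direction and its side of the threshold. A count was alike if it lay within 1.5 times the reported count. A value without a test counted as moved if it differed at all and kept its sign. Of the named genes, regions, motifs and lists, 2130 values under these alternatives were alike, 183 lost and 13 gained significance, 82 moved and 139 turned. When a library was left out, the same counts were 209, 119 and 8 for the first kind, and 3463, 255, 13, 264 and 113 for the second. Gains and losses rise by construction when a library is left out, since 2 libraries then define a group. For the other values that follow the cause was not tested, unless the setting itself leaves fewer peaks, genes or libraries. The search for sequence motifs in gained regions, with its alternatives, was not run, since it needs a genome. The lists hold calls and no read totals, so a region with few fragments can be missed in any library. In simulated data TCDD changes were placed in genes with at least 5 regions. The gene test found 1 of 100 genes at odds of 4 and 16 of 100 at odds of 20. No rate of detection was simulated for the other comparisons.

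Peak number in Tryp against vehicle differed by 107 with stricter peaks and 5199 with wide peaks. Wide peaks gave -489 for TrypCH against Tryp, -5.33 for TCDD against vehicle and 242 for agonist against the other libraries. Leaving out a library gave -10386 to 12703 for Tryp against vehicle and -6087 to 7350 for the agonist contrast. TCDD against vehicle was 37828 without TCDD 1 and 13982 without TCDD 2, and TrypCH against Tryp was 9952 without Tryp 2.

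Lists of equal number gave gains of 723 for TrypCH against Tryp, 2734 for TCDD against vehicle and 702 for TrypCH against vehicle, and losses of 866, 2853 and 812. Stricter peaks gave losses of 116 for TrypCH against Tryp and 75 for TrypCH against vehicle. Where peaks had to cover 50% of a region, gains of Tryp over vehicle were 896, and losses were 1540, 3279 and 1041 in TrypCH against Tryp, TCDD against vehicle and TrypCH against vehicle. Wide peaks gave gains of 783, 651, 2215 and 1140 in Tryp against vehicle, TrypCH against Tryp, TCDD against vehicle and TrypCH against vehicle, and losses of 994, 2253 and 529 in the last 3. With at least 2 of 3 libraries against 0 of 3 the gains were 4201, 8549, 17289 and 11205 in that order, and the losses 2409, 1878, 3528 and 1498. Without 1 library the gains ranged from 695 to 3378, 3029 to 7903, 5512 to 15556 and 5495 to 7434, and the losses from 396 to 1480, 318 to 1325, 1457 to 2126 and 288 to 866.

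Regions higher with agonist numbered 912 where peaks had to cover 50% of a region. With 6 of 6 against 0 of 6 libraries 9 were higher and 11 lower. Without 1 library 620 to 2124 were higher and 724 to 1696 lower. The LOC388780 region turned to -16.7 percentage points with wide peaks. The overlap of gains of TCDD over vehicle with Tryp over TrypCH was 33 with lists of equal number, 25 at 50% cover, 30 with wide peaks and 281 with at least 2 of 3 libraries. Independent lists give 35.8, 44.7, 24.4 and 244 there, and Fisher's exact test gave p = 0.731, 0.00168, 0.256 and 0.0116, so the overlap lay below independence at 50% cover and above it with at least 2 of 3. The overlap of losses in that pair was 24, 18 and 222 with equal number, 50% cover and at least 2 of 3, where independent lists give 31.2, 51.1 and 227 (Fisher's exact test, p = 0.230, 1.06e-07 and 0.781). Against the shared vehicle, gains overlapped in 2107 regions with at least 2 of 3, and losses in 24 with stricter peaks, 106 with equal number, 114 at 50% cover, 97 with wide peaks and 695 with at least 2 of 3. Without 1 library these 4 overlaps ranged from 9 to 97, 11 to 72, 113 to 753 and 45 to 349.

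Genes past the threshold in TCDD against vehicle numbered 131 with stricter peaks, 245 with lists of equal number, 63 with wide peaks, 2 with raw numbers, 0 within 50 kb, 18 with at least 1 region, 1 with only the groups compared and 2 with TCDD by its first library alone. For the agonist contrast the same settings gave 70, 57, 6, 0, 1 and 4, at least 5 regions gave 31, and TCDD by its first library alone 3. In TrypCH against Tryp stricter peaks and at least 5 regions each gave 1. Without 1 library the numbers ranged from 0 to 2 in Tryp against vehicle, 0 to 3 in TrypCH against Tryp, 0 to 39 in TCDD against vehicle, 0 to 8 in TrypCH against vehicle and 0 to 13 in the agonist contrast.

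TIPARP (0.0640) changed sign in Tryp against vehicle with stricter peaks. EREG (-0.0632) changed sign in TrypCH against Tryp with stricter peaks. PSD2 (0.287) changed sign in TCDD against vehicle with stricter peaks. CYP1A1 (0.305) changed sign in TrypCH against vehicle with stricter peaks. TIPARP (0.00811) changed sign in agonist against the other libraries with stricter peaks. KRT8 (0.00457), SERPINB2 (0.00438) and TIPARP (0.00644) changed sign in Tryp against vehicle with lists of equal number. CCND1 (-0.245), LOC285692 (0.198), SERPINB2 (0.0516) and THY1 (-0.543) changed sign in TrypCH against Tryp with lists of equal number. CLDN5 (0.409), KRT8 (0.0543), RNU6ATAC (0.411) and TIPARP (0.0761) changed sign in TCDD against vehicle with lists of equal number. ATXN1 (-0.0833), BANF2 (0.481), SERPINB2 (0.0560) and SLC7A5 (0.0888) changed sign in TrypCH against vehicle with lists of equal number. ALDH1A3 (-0.323), CCND1 (0.00376), THY1 (0.506) and TIPARP (0.502) changed sign in agonist against the other libraries with lists of equal number. CYP1B1 (0.739) and KRT8 (0.108) changed sign in Tryp against vehicle with wide peaks. COL13A1 (-0.300), EREG (-0.451) and SERPINB2 (0.854) changed sign in TrypCH against Tryp with wide peaks. AHRR (0.786), ALDH3A1 (0.0833), CLDN5 (0.775), CXCL8 (-0.915), CYP2S1 (0.0881) and NQO1 (-0.264) changed sign in TCDD against vehicle with wide peaks. ATXN1 (-0.0436), BANF2 (0.537) and COL1A2 (-1.18) changed sign in TrypCH against vehicle with wide peaks. CXCL8 (-0.175), MIR4279 (0.305), NQO1 (-0.511) and RBMS3-AS3 (0.153) changed sign in agonist against the other libraries with wide peaks. CYP1A1 (0.333), SERPINB2 (0.667) and TIPARP (0.667) changed sign in TrypCH against Tryp with raw numbers. AHRR (1) and SLC7A5 (0.333) changed sign in TCDD against vehicle with raw numbers. CYP1A1 (0.667), EREG (1.33), NQO1 (0.333), SLC7A5 (0.333) and TIPARP (0.333) changed sign in TrypCH against vehicle with raw numbers. TIPARP (0.0237) changed sign in Tryp against vehicle within 50 kb. AHRR (0.102) changed sign in TCDD against vehicle within 50 kb. EPAS1 (0.0696), NQO1 (-0.0655), THY1 (0.0940) and TIPARP (0.0163) changed sign in agonist against the other libraries within 50 kb.

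Leaving out 1 library at a time turned the sign of these genes. ALDH3A1 ran from -0.753 to 0.0491, CYP1A1 from -0.486 to 0.819, CYP1B1 from -0.788 to 0.0738, CYP2S1 from -0.0686 to 0.555 and TIPARP from -0.548 to 0.0541 in Tryp against vehicle. CYP1A1 ran from -0.957 to 0.376, EREG from -0.0286 to 1.37, NQO1 from -0.626 to 0.782 and TIPARP from -0.254 to 0.159 in TrypCH against Tryp. AHRR ran from -0.884 to 0.289 and NQO1 from -0.392 to 2.26 in TCDD against vehicle. AHRR ran from -0.188 to 0.924, CYP1A1 from -0.564 to 0.290 and EREG from -1.35 to 0.403 in TrypCH against vehicle. NQO1 ran from -0.315 to 1.12 in agonist against the other libraries.

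Motifs past the threshold in TCDD against vehicle numbered 17 on the logit scale, 4 without the filter, and 0 with only the groups compared or with TCDD by its first library alone. For TrypCH against Tryp they numbered 2 without the filter and 0 with only the groups compared or with peak number as a covariate. For TrypCH against vehicle they numbered 0 on the logit scale, 6 without the filter, and 2 with a pseudocount of 0.1 or with peak number as a covariate, and for Tryp against vehicle 1 with that covariate. Without 1 library the numbers ranged from 0 to 2, 0 to 1, 1 to 52, 0 to 3 and 0 to 1 in Tryp against vehicle, TrypCH against Tryp, TCDD against vehicle, TrypCH against vehicle and the agonist contrast. AP-1 (0.096), Npas4 (0.013), TEAD1 (0.069) and TEAD3 (0.13) changed sign in Tryp against vehicle on the logit scale. CTCF (0.032) changed sign in TrypCH against Tryp on the logit scale. BORIS (-0.068), NPAS (0.069), TEAD (0.019), TEAD4 (0.039) and p63 (0.066) changed sign in TCDD against vehicle on the logit scale. BORIS (-0.047) and p63 (0.017) changed sign in TrypCH against vehicle on the logit scale. CTCF (-0.041), NFE2L2 (-0.019) and Npas4 (0.0063) changed sign in agonist against the other libraries on the logit scale. BORIS (-0.0038), CTCF (0.28), Npas4 (-0.11) and TEAD3 (-0.029) changed sign in TCDD against vehicle with TCDD by its first library alone. HIF-1a (0.033) changed sign in agonist against the other libraries with TCDD by its first library alone. AP-1 (0.0069) and TEAD3 (0.0011) changed sign in Tryp against vehicle with peak number as a covariate. AP-1 (-0.051), CTCF (0.18) and Npas4 (-0.018) changed sign in TrypCH against Tryp with peak number as a covariate. CTCF (0.18) and Npas4 (-0.044) changed sign in TCDD against vehicle with peak number as a covariate. AP-1 (-0.044), BORIS (-0.0080) and Npas4 (-0.032) changed sign in TrypCH against vehicle with peak number as a covariate. CTCF (-0.0016) changed sign in agonist against the other libraries with peak number as a covariate.

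Leaving out 1 library at a time turned the sign of these motifs (log2 ratio). AP-1 ran from -0.048 to 0.069, Arnt:Ahr from -0.071 to 0.050, CTCF from -0.036 to 0.23, HIF2a from -0.040 to 0.21, NPAS from -0.029 to 0.097 and NPAS2 from -0.089 to 0.020 in Tryp against vehicle. Npas4 ran from -0.048 to 0.010, TEAD from -0.018 to 0.091, TEAD2 from -0.039 to 0.078, TEAD3 from -0.060 to 0.058 and TEAD4 from -0.045 to 0.077 in Tryp against vehicle. CTCF ran from -0.18 to 0.083, HIF-1a from -0.021 to 0.18, HIF-1b from -0.092 to 0.054, HIF2a from -0.076 to 0.17 and p63 from -0.0085 to 0.094 in TrypCH against Tryp. BORIS ran from -0.069 to 0.090, CTCF from -0.17 to 0.15, HIF-1a from -0.0033 to 0.12 and Npas4 from -0.022 to 0.082 in TCDD against vehicle. TEAD ran from -0.054 to 0.026, TEAD3 from -0.013 to 0.050 and TEAD4 from -0.065 to 0.057 in TCDD against vehicle. BORIS ran from -0.032 to 0.038, HIF-1a from -0.081 to 0.013 and NFE2L2 from -0.019 to 0.19 in TrypCH against vehicle. CTCF ran from -0.059 to 0.10, HIF-1a from -0.071 to 0.032, HIF2a from -0.024 to 0.099, NFE2L2 from -0.051 to 0.11 and Npas4 from -0.039 to 0.013 in agonist against the other libraries.

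Lists past the threshold numbered 3 with stricter peaks and 1 by limma over lists. Fisher's exact test of list regions among gained and lost regions, which treats regions as independent and was not used as a result, gave 0 of 176 past the threshold, 11 at an unadjusted p under 0.05 and a smallest adjusted p of 0.504. Endothelial markers (-0.292) changed sign in agonist against the other libraries with raw shares. Neuronal markers (5.70) changed sign in TrypCH against Tryp with raw shares. Epithelial junction and simple keratins (2.20), immune checkpoints (3.85) and chromatin regulators (2.36) changed sign in TCDD against vehicle with raw shares. Neuronal markers (0.877) changed sign in TrypCH against vehicle with raw shares. AHR target battery (-10.6), mesenchymal transition (-0.937), matrix proteases (4.97) and interferon and antigen presentation (7.52) changed sign in agonist against the other libraries with promoters only. Immune checkpoints (6.40), YAP-TEAD and TGF-beta (6.58), stemness (-9.64) and endothelial markers (-1.61) changed sign in agonist against the other libraries with promoters only. Immune checkpoints (25.7) and immune cell markers (-14.1) changed sign in TCDD against vehicle with promoters only. AP-1 and MAF factors (-18.8), cell cycle (-19.4) and chromatin regulators (-15.7) changed sign in TrypCH against vehicle with promoters only. AHR pathway components (0.374), matrix proteases (1.71), immune checkpoints (0.339), stemness (-1.55) and endothelial markers (-0.943) changed sign in agonist against the other libraries with stricter peaks. Tryptophan metabolism and transport (-1.52), NRF2 antioxidant (-3.41), immune checkpoints (6.35), AP-1 and MAF factors (0.0743) and cell cycle (4.85) changed sign in agonist against the other libraries with lists of equal number. Housekeeping (0.851), fibroblast markers (1.37), immune cell markers (-2.96) and neuronal markers (-2.0) changed sign in agonist against the other libraries with lists of equal number. Cell cycle (-2.52) and fibroblast markers (-3.0) changed sign in TrypCH against Tryp with lists of equal number. Immune checkpoints (3.29) and immune cell markers (-6.83) changed sign in TCDD against vehicle with lists of equal number. AP-1 and MAF factors (-2.04) and chromatin regulators (-4.72) changed sign in TrypCH against vehicle with lists of equal number. NRF2 antioxidant (-0.746), keratinocyte differentiation (2.00), matrix proteases (0.294), interferon and antigen presentation (4.39), immune checkpoints (0.386), AP-1 and MAF factors (3.31) and housekeeping (2.00) changed sign in agonist against the other libraries with wide peaks. Fibroblast markers (-0.274) changed sign in TrypCH against Tryp with wide peaks.

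Leaving out 1 library at a time turned the sign of these lists (percentage points). AHR target battery ran from -2.0 to 3.49, NRF2 antioxidant from -0.565 to 2.83, basal squamous identity from -0.225 to 3.22, YAP-TEAD and TGF-beta from -1.48 to 0.684, endothelial markers from -0.771 to 1.75 and neuronal markers from -0.480 to 3.37 in agonist against the other libraries. Promoter-TSS (-0.0402) and intron (0.0124) changed sign in agonist against the other libraries with lists of equal number. Without 1 library the annotation shares turned as follows. Promoter-TSS ran from -0.218 to 0.258, intron from -0.149 to 0.0148, Intergenic from -0.0320 to 0.336 and TTS from -0.0147 to 0.00258 in agonist against the other libraries.

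The treatments share replicate numbers, and deviations from the group means correlated at 0.00967 on average (-0.0145 to 0.0579) between libraries with the same number and at -0.00483 between those with different numbers. Of the 12 libraries 7 correlated best with their own number, a hint of pairing from the data. The numbers were not taken to pair the libraries, since no pair correlated above 0.1 and no label gives a shared batch or day. These correlations and the replicate block used the numbers of the titles. Pairing by the numbers in the library names, which differ for vehicle 2 and vehicle 3, was not tested. With the replicate block 49 genes passed in TCDD against vehicle, 1 in TrypCH against Tryp, and 17 in the agonist contrast. The replicate block gave 1 motif in Tryp against vehicle and 2 in TrypCH against vehicle. It moved no other number of genes, motifs, lists or annotation classes past the threshold by over 1.5 times. Regions higher in the agonist libraries of every replicate block numbered 4069 and regions lower 3398, under a looser criterion by construction.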

Other observations

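The test of short fragments in regions gained with TCDD was set before its result was seen, and the other tests below were chosen after the results they bear on were seen.

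Within single comparisons the NRF2 antioxidant list, genes of the response to oxidative stress, had a higher share of called regions in TCDD than in vehicle (7.90 percentage points, exact permutation p = 0.1, n = 3 and 3) and in TrypCH than in Tryp (5.74). In TCDD against vehicle the epithelial junction and simple keratin list (-9.74), chromatin regulators (-9.60) and immune checkpoints (-6.03) were lower, but with raw shares they stood at 2.20, 2.36 and 3.85, and with lists of equal number immune checkpoints stood at 3.29. Without vehicle 3 the epithelial list stood at -6.20. Immune cell markers were higher (7.76), against -6.83 with lists of equal number and 5.03 without vehicle 2. With promoters only, immune checkpoints stood at 25.7 and immune cell markers at -14.1. In TrypCH against Tryp, fibroblast markers (10.1), chromatin regulators (9.24), cell cycle genes (9.16) and keratinocyte differentiation (3.74) were higher and neuronal markers lower (-5.29), while with lists of equal number fibroblast markers were -3.0 and cell cycle genes -2.52, and with raw shares neuronal markers were 5.70. Keratinocyte differentiation was 2.34 without Tryp 3. In TrypCH against vehicle, AP-1 and MAF factors (11.5), cell cycle genes (8.39) and chromatin regulators (5.10) were higher and neuronal markers lower (-11.4). Lists of equal number gave AP-1 and MAF factors -2.04 and chromatin regulators -4.72, and raw shares gave neuronal markers 0.877. With promoters only, AP-1 and MAF factors were -18.8, cell cycle genes -19.4 and chromatin regulators -15.7. In Tryp against vehicle, housekeeping genes (-11.1) and neuronal markers (-6.07, and -3.58 without vehicle 1) were lower and immune checkpoints higher (3.94). Each of these values had the smallest p that 3 against 3 libraries allow in that test, 0.1, which chance alone gives 10% of lists. Inflammatory cytokines had a larger value in TCDD against vehicle, 13.9 points (exact permutation p = 0.2), with 12.9 in lists of equal number and 8.31 without TCDD 1. In the limma fit over lists 0 of 22 passed in any of the 4 comparisons, and 1 list had an unadjusted p under 0.05 in Tryp against vehicle, 4 in TrypCH against Tryp, 4 in TCDD against vehicle and 3 in TrypCH against vehicle. The smallest adjusted p was 0.0680, for AP-1 and MAF factors and for neuronal markers in TrypCH against vehicle. In TCDD against vehicle chromatin regulators, NRF2 antioxidant genes, the epithelial junction list and cytokines had an adjusted p of 0.101, while immune checkpoints in Tryp against vehicle had an unadjusted p of 0.264.

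Genes that passed in TCDD against vehicle outside the naming rule, chosen after their values were seen, included GRB10, an adaptor of insulin receptor signalling (4.02 regions), HS3ST1, a heparan sulfate sulfotransferase (3.77), and TNFSF18, a ligand of the tumour necrosis factor family (3.97). In the other direction were GLDC, the glycine decarboxylase gene (-5.66), BTBD3 (-4.22), KLHL13 (-2.87) and L1TD1 (-3.38). All had limma adjusted p-values between 0.0434 and 0.0475. At the TIPARP promoter (chromosome 3, 156673857 to 156674972, GRCh38), called in all 12 libraries, the authors' folds were 17.4, 19.5 and 18.3 with TCDD and 15.9, 16.2 and 16.4 with vehicle, and were not tested. Regions gained with TCDD had a median length of 267 bp and regions lost 424 bp. Across 13628 genes, which are not independent replicates, the values of TCDD minus vehicle and of Tryp minus TrypCH had a Pearson correlation of 0.0515. The sign depended on the pairing, with -0.0506 for TCDD minus TrypCH and Tryp minus vehicle, and 0.0986 for TCDD minus Tryp and vehicle minus TrypCH.

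The regions that set TCDD apart from vehicle were 3.33 times as many as the calling rates give, and lists of different length are argued against, since lists of equal number gave 5.75 times the expected total and at most 0.880 in the other splits of the 6 libraries. Short fragments in TCDD 2 and TCDD 3, a reading of their smallest peak widths, are argued against for the losses: TCDD 1, whose smallest peak is wider, missed 79.1% of the 1457 regions called in all vehicle libraries and in neither TCDD 2 nor TCDD 3, against 49.3% in Tryp 2 and 17.6% or less in Tryp 1 and Tryp 3. For the gains short fragments and TCDD cannot be told apart, because TCDD 1 called 31.5% of the 15556 regions called in TCDD 2 and TCDD 3 and no vehicle library, as did Tryp 3 (31.4%), though Tryp 1 called 18.2% and TCDD 1 calls fewer regions in general. TrypCH 1, 2 and 3, with smallest widths of 123, 122 and 126 bp, called 26.8%, 26.0% and 42.4% of these regions. They also call more regions in general than TCDD 1. With wide peaks, which leave out narrow peaks of all libraries, there were 2215 gains and 2253 losses, 4.12 times the expected total (highest other split 1.08). The losses numbered 1152 without this filter. It takes more calls from libraries with narrow peaks, such as TCDD 2 and TCDD 3, which can itself raise losses. The wide peaks are also a part of the peaks, so this setting does not decide on short fragments. A response to TCDD stays open as a hypothesis, and the 10 splits of 6 libraries are too few to judge chance (3.33 against a highest other value of 0.892 for regions, 30 against 1 for genes, 1 against 0 for motifs).

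Regions that differed between TrypCH and Tryp were mostly called in TrypCH (92.8%), as were those between TrypCH and vehicle (95.6%). These shares were 45.5% and 46.4% in lists of equal number, but trimming to the same length pushes gains and losses towards balance whatever the cause. Longer lists in TrypCH and an opening of chromatin by the inhibitor therefore cannot be told apart by these shares. In lists of equal number the total was 2.53 times the expected one for TrypCH and Tryp (highest other split 1.04). For TrypCH and vehicle it was 2.55 times (highest other split 1.06). These totals argue against lists of different length for the size of the excess, and leave its direction open. Whether the inhibitor lengthened the lists was not tested. The 10 splits are too few to judge chance, with 1.79 against a highest other value of 1.01 for TrypCH and Tryp and 1.83 against 1.05 for TrypCH and vehicle.

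Regions linked to the agonists reached 2.66 times the expected number, and of 100 drawn splits of the 12 libraries only the real one reached that (highest other 2.63). The excess was not particular to that division. TCDD and vehicle as one arm are the libraries without the metabolite pool. That arm gave 2.85 times the expected number (1316 regions against 1190), and TCDD and TrypCH gave 1.72. A region called in the TCDD libraries alone cannot meet the criterion, so these values do not decide on changes in TCDD alone. Regions gained with TCDD and higher in Tryp than in TrypCH numbered 9 where independent lists give 8.03, with an exact Poisson interval up to 2.13 times that, and the mirror losses numbered 11 against 24.3 (Fisher's exact test, p = 0.00372), where the calling rates of the 12 libraries give 1.56 and 3.12. Losses were 24 against 31.2 in lists of equal number (Fisher's exact test, p = 0.230) and 18 against 51.1 at 50% cover, and gains were 281 against 244 with at least 2 of 3 libraries (p = 0.0116) and 25 against 44.7 at 50% cover (p = 0.00168). Since these baselines and settings differ in direction, a response shared by TCDD and Tryp and blocked by the inhibitor cannot be told apart from its absence.

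For genes past the threshold, the agonist contrast gave 19 and the highest of the other drawn splits 1, with 1 of 100 splits as large. The drawn splits scatter the libraries of a treatment, which raises the spread within the groups of the fit, so they say little about chance for that number. With treatments kept whole, TCDD and vehicle as one arm, the libraries without the metabolite pool, gave 38 genes. TCDD and TrypCH gave 0, and this comparison was made after the number was seen. The number was also 0 without vehicle 3 and with raw numbers of regions, and 1 within 50 kb. For motifs in that contrast the real number was 0, which all 100 splits reach by construction, so the splits say nothing about chance. The highest of them gave 13, which may point to a structure of the samples, though none was identified or tested. In Tryp against vehicle, 2 of 10 splits had a regional excess as large (1.18 against a highest other value of 1.21), and the splits are too few to judge chance there. A real number of 0, reached by 10 of 10 splits by construction, likewise says nothing about chance for genes in Tryp against vehicle (highest other 1), TrypCH against Tryp (0) and TrypCH against vehicle (0), or for motifs in Tryp against vehicle (1). For motifs in TrypCH against Tryp and in TrypCH against vehicle the values were 1 against 0, and the splits are too few.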
